A study of Mus musculus with 27 samples.

How the data were processed

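Sperm DNA of 27 libraries was digested with MspI, bisulfite converted and sequenced, per the labels' protocols. The labels list Trim Galore 0.3.3, BSMAP 2.74, Picard and the mouse build mm10 in the submitters' processing notes, without the role or order of the tools. Each library has its own list of CpG cytosines. The coverage column holds the read count at each cytosine, per the file headers, with a highest value of 65535. The methylated and unmethylated shares are given as percent of those reads, per the file headers. The caller, its filters and any removal of duplicate reads are not stated in the labels. The number of methylated reads was taken as coverage times percent, rounded. The product was a whole number, to within 0.1 points of percent, for at least 99.8% of positions with few reads in every library.

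Both strands of a CpG were merged, positions on chromosomes 1 to 19, X and Y were kept, and CpGs were grouped in tiles of 100 bp (2,382,769 CpGs in 767,742 tiles over all libraries). A tile was tested when it held 2 or more CpGs and 15 or more reads in every library of the fit. Libraries held 14.7 to 131 M reads at CpGs, and 1,861,888 to 3,101,796 positions. The first-cohort fit had 128,821 tiles (median 193 reads per tile and library), the second-cohort fit 133,510 (276) and the fit of the 4 wild-type groups 82,925 (305).

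Methylated and unmethylated reads were compared with a quasi-binomial logistic model per tile with 1 coefficient per group. The dispersion between libraries was moderated across tiles with the method of limma's squeezeVar, with a floor of 1, and tested with an F test and Benjamini-Hochberg adjustment over all tiles. The moderation was written in Python and checked against limma 3.58.1, from which it differed by 0. A tile was called at an adjusted p under 0.05 and an unweighted difference of group means of 10 or more percentage points. The 20 first-cohort libraries entered 1 fit with 4 group terms for the diet, genotype and interaction comparisons. The 7 second-cohort libraries entered a fit of their own, and the 4 wild-type groups a fit for the difference between the 20-fold and 10-fold effects. Genotype over both diets and diet over both genotypes were added after the data were examined.

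Each library's unweighted mean was compared between groups by two-sided exact permutation tests over all tiles, over tile classes and over 7 gene lists. Benjamini-Hochberg adjustment was over the 5 comparisons of 2 groups for all tiles and for each tile class, without adjustment over the classes, and over the lists within a comparison for gene lists. The interaction of such means was tested by permuting diet labels within genotypes, with adjustment over 13 values. The classes were tiles with a mean below 20%, of 20 to 80% and above 80%, tiles with 5 or more CpGs, within a gene, outside genes, within 1 kb of a gene end, and autosomes, X and Y. Gene positions came from a RefSeq gene list of assembly GRCm38.p6, the assembly that mm10 names, which gives no strand, exons or repeats. Promoter, exon, intron and repeat classes were therefore not computed. The lists held folate and one-carbon genes (38 genes, 32 with tiles), DNA methylation machinery (21, 20 with tiles), germline genes (26, 26 with tiles), spermatid genes (25, 15 with tiles), developmental regulators (84, 84 with tiles), maternally methylated imprinted promoters (16, 12 with tiles) and paternally methylated imprinted regions (4, with tiles for 0, hence not compared). A list took tiles in the gene body and within 5 kb of either end, since the upstream side could not be told, except for imprinted promoters, for which the strand was typed in from general knowledge.

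Before the data were examined, the comparisons, tests, alternatives and the rule for naming tiles were fixed. For each comparison, up to 12 called tiles with the largest gain and 12 with the largest loss were named, among those whose groups did not overlap. Every called tile of a listed gene was named too, as were the tiles of Mthfr. Where no tile was called, the 5 tiles with the smallest p were named. Tiles outside genes are given by their nearest gene and the distance. The share of called tiles within 20 Mb of Mthfr and overlaps of called tiles were tested with Fisher's exact test. Only comparisons that set no library in common were overlapped. The overlap of the genotype lists of the control and 10-fold diets was added after the data were examined. First-cohort comparisons share the estimate of spread. The genotype lists were therefore also overlapped from a separate fit of each diet's 2 groups, likewise added after the data were examined.

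The model was tested on simulated data made from each fit's own coverage, means and spread, with 200 tiles changed by 10, 20 or 40 points. For heterozygous against wild-type controls it recovered 13.4%, 38.8% and 83.3% of them, with 5 false calls among 128,621 unchanged tiles. The changes were gains only, in tiles of low or moderate mean methylation, so recovery of losses was not measured. Each tile and library was drawn independently. False calls from shifts that many tiles of a library share were therefore not measured. Alternatives were other coverage minimums (10 and 30 reads), other minimum differences (20 points or none), no minimum of CpGs, single CpGs, the compared groups alone, and limma on log2((methylated reads + 1)/(unmethylated reads + 1)), with and without centring each library. Further ones were a chi-square test on pooled reads, the replicate number and the library number as blocks, and leaving out each library or replicate number. After the data were examined, a depth block (libraries above or below 50 M reads), the share of CpG reads in tiles with 8 or more CpGs as a covariate, and a restriction to tiles with a mean of 5 to 95% were added. Other splits of the libraries were all 35 for the second cohort and 100 drawn ones elsewhere. Pearson and Spearman correlations used 100000 permutations. Reads on unplaced sequences were not used in the comparisons. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and the R package data.table (version 1.17.8) were used.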

Results

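Methylation of cytosines at CpG sites was measured by reduced representation bisulfite sequencing in sperm of BALB/c mice. The mice were wild type or heterozygous for a targeted inactivation of Mthfr, the gene of the enzyme that makes 5-methyltetrahydrofolate. In the first cohort, each genotype received a control diet or a diet with 10-fold folic acid, with 5 libraries in each of the 4 groups. In the second cohort, wild-type mice received a control diet (4 libraries) or 20-fold folic acid (3 libraries). These controls are titled newCD, and the division into cohorts was taken from the titles. Diets lasted 6 to 12 months, and each treated group has its own controls. The labels do not say whether each library comes from a separate animal.

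The libraries held 14.7 M reads at CpG positions (heterozygous 10-fold replicate 3) to 131 M reads (wild-type 20-fold replicate 3). The ranges in M reads were 19.7 to 128 in wild-type controls, 23.6 to 91.5 in heterozygous controls, 22.2 to 102.9 in the wild-type 10-fold group and 14.7 to 116 in the heterozygous 10-fold group. They were 51.6 to 92.7 in second-cohort controls and 81.2 to 131 in the 20-fold group. The median position carried 5 to 32 reads, depending on the library. In the first cohort, 128,821 tiles of 100 bp had 15 or more reads in all 20 libraries, with a median of 193 reads per tile and library. The share of CpG reads in tiles with 8 or more CpGs also varied: 46.9% ± 7.43 (SD, n = 5) in wild-type controls, 39.3% ± 5.74 in heterozygous controls, 45.6% ± 4.99 in the wild-type 10-fold group and 46.3% ± 7.21 in the heterozygous 10-fold group. It was 69.0% ± 1.48 (n = 4) in second-cohort controls and 77.4% ± 2.08 (n = 3) in the 20-fold group. A tile below is called when its adjusted p from the quasi-binomial model was under 0.05 and its group means differed by 10 or more percentage points.

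Within the targeted gene, 2 of 10 tiles differed between genotypes. At the Mthfr tile on chromosome 4, 148040101 to 148040200 (mm10), which holds 2 CpGs, methylation was 93.7% ± 2.84 (SD, n = 5; range 89.7 to 97.4) in wild-type controls and 94.0% ± 2.81 (90.9 to 97.2) in the wild-type 10-fold group. It was 75.5% ± 8.64 (65.5 to 82.2) in heterozygous controls and 71.3% ± 6.25 (61.4 to 76.7) in the heterozygous 10-fold group. All 10 heterozygous libraries lay below all 10 wild-type libraries, from 15 to 235 reads per library. On the 10-fold diet the genotype difference was -22.7 points (SE 3.06, adjusted p 0.00389), and on the control diet -18.1 points (adjusted p 0.101). The neighbouring Mthfr tile at 148040201 was lower by -11.8 points over both diets (adjusted p 0.0218), and was not called when any replicate number was left out. At both Mthfr tiles 1 of the 2 CpGs carried the difference. Over the 13 tiles of the gene and its 5 kb flanks, heterozygous sperm differed by -1.54 points on the control diet (exact permutation p 0.135) and -4.25 on the 10-fold diet (exact permutation p 0.127).

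The comparison of heterozygous with wild-type sperm on the control diet asks what the Mthfr mutation changes without added folic acid. It gave 51 called tiles, 47 higher and 4 lower in heterozygous sperm. Of the 2454 tiles with an unadjusted p under 0.05 and 10 or more points, 2379 were higher. The largest gain lay 2674 bp from the pseudogene Gm5363 (chromosome 9, 4210601 to 4210700), where methylation was 9.84% ± 4.18 (SD, n = 5) in wild-type and 77.3% ± 7.53 in heterozygous controls. That is a difference of 67.5 points (SE 3.85, adjusted p 6.86e-06). Near Fam71a (chromosome 1, 191157401 to 191157500, 5084 bp from the gene), methylation was 33.8% ± 13.4 in wild-type and 94.5% ± 2.79 in heterozygous controls, 60.7 points higher (adjusted p 3.08e-06). Near Septin8, the gene of a cytoskeletal GTPase (chromosome 11, 53555701 to 53555800, 6096 bp away), it was 21.4% ± 8.56 against 74.7% ± 7.16, a difference of 53.3 points (adjusted p 3.08e-06). Near Slc22a4, an organic cation transporter gene (chromosome 11, 54035501 to 54035600, 5461 bp away), it was 31.4% ± 7.73 against 83.4% ± 4.56, 52.0 points higher. The other large gains lay near Gm5997 (58.2 points), Gm22433 (53.8), Gm4960 (47.8), the PRAME-family gene Pramel27 (46.8) and the olfactory receptor gene Olfr811 (45.2), and within Gm26567 (44.8). A Gm26567 tile at 88626101 lost its call without any one of 5 of the 10 libraries (adjusted p up to 0.215).

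Of the 4 losses, the largest lay 12173 bp from Gm6308 (chromosome 6, 124285501 to 124285600), with 92.8% ± 6.39 in wild-type and 50.1% ± 11.7 in heterozygous controls, a difference of -42.8 points (adjusted p 0.0232). It was not called without wild-type control replicate 1, 2 or 3 (adjusted p up to 0.213). Near Gm32427 on chromosome 14 (tile 43812101), the difference was -25.2 points (adjusted p 0.00274). Within the zinc finger gene Zfp982 on chromosome 4 (tile 147472301), it was -14.8 points, from 94.8% ± 2.05 to 79.97% ± 3.73 (adjusted p 0.00250). Near Gm13223 on chromosome 4 it was -10.1 points (adjusted p 0.0302), and that call ended on leaving out any one of 8 of the 10 libraries. The total of 51 fell to 20 without wild-type control replicate 2, 23 without wild-type control replicate 3 and 21 without heterozygous control replicate 2. It was 18 with the share of reads in CpG-dense tiles as a covariate.

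**Figure D1:**
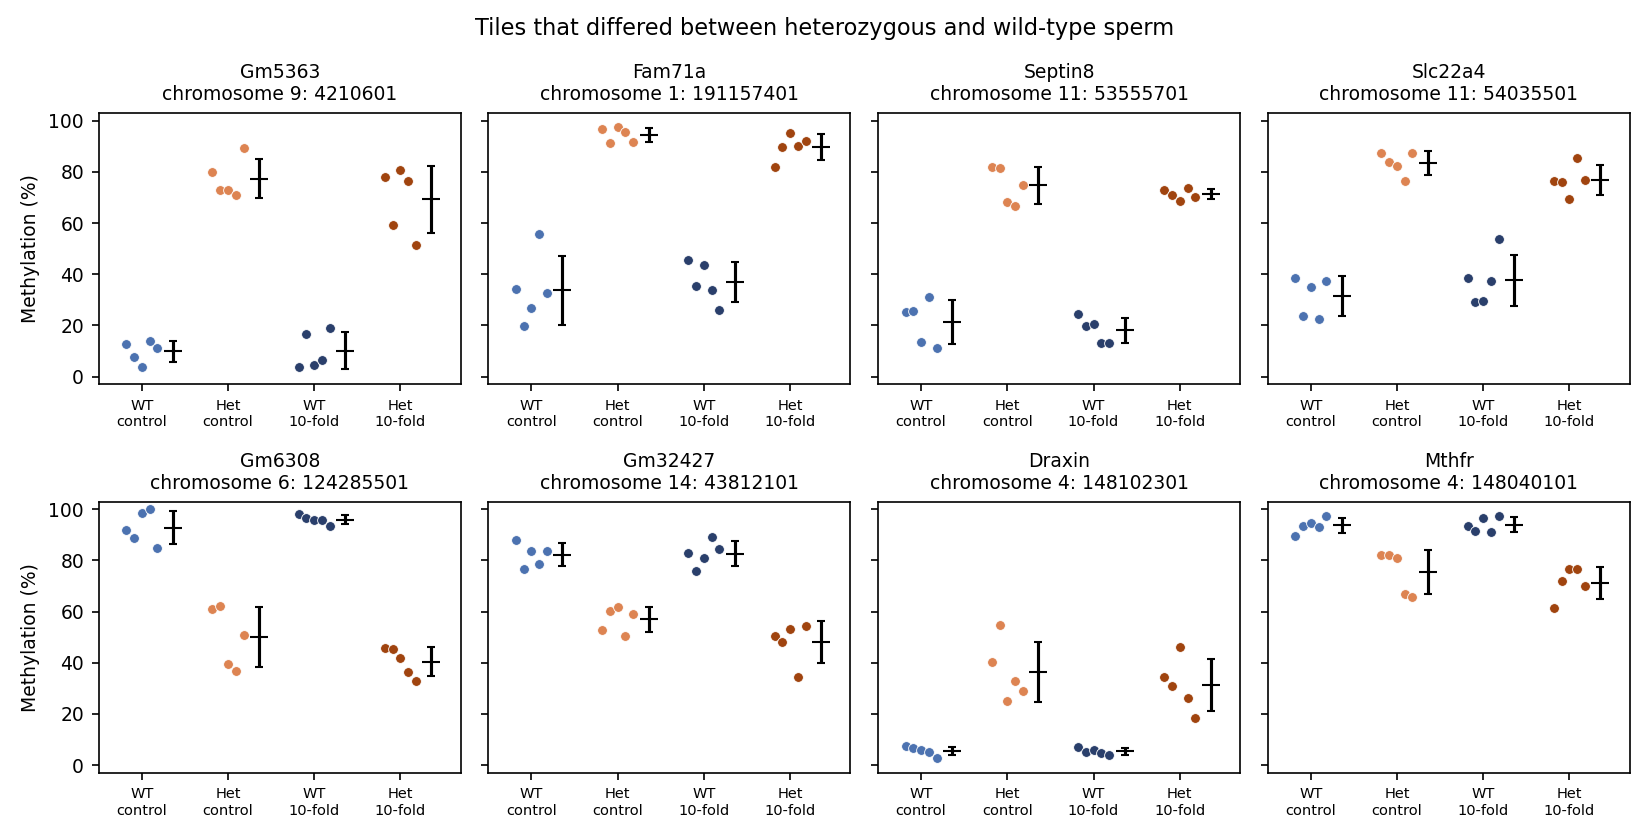
Methylation (%) of named tiles in each first-cohort library (points), with group means and SD (bars). At the tile near Gm5363, heterozygous controls averaged 77.3% and wild-type controls 9.84%.

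The same genotype comparison on the 10-fold diet sets other libraries against each other, within the same fit, whose spread comes from all 20 libraries. It gave 18 called tiles, 15 higher and 3 lower in heterozygous sperm. The direction was the opposite among the 681 tiles with an unadjusted p under 0.05 and 10 or more points, with 79 higher and 602 lower. Of the 15 higher called tiles, 14 were also among the 47 higher on the control diet, where 0.00547 would be shared by independent lists (Fisher's exact test, p 1.29e-48). This overlap of the genotype lists was added after the data were examined. Fisher's test counts neighbouring tiles as independent, so its p for the overlaps can be too small. Both lists also shared 2 lower tiles, at Gm6308 and Gm32427. With a separate fit for each diet, which shares no library and no estimate of spread, 11 tiles were called on the control diet and 4 on the 10-fold diet. Of these, 3 higher tiles were shared (0.000256 by independent lists, Fisher's exact test, p 4.63e-13). No lower tile could be shared, since 0 lower tiles were called on the control diet in these fits. Methylation near Gm5363 was 10.1% ± 7.27 (SD, n = 5) in wild-type and 69.2% ± 13.05 in heterozygous sperm, 59.1 points higher (adjusted p 0.000786). Near Septin8 it was 18.04% ± 4.97 against 71.3% ± 2.08, 53.3 points higher (adjusted p 0.000128). Near Fam71a it was 36.9% ± 7.90 against 89.7% ± 4.92, 52.8 points higher. Near Gm6308 it was 95.9% ± 1.79 against 40.4% ± 5.56, a difference of -55.5 points (adjusted p 0.000399). The 3 Septin8 and Fam71a tiles, the Gm5363 tile and the Mthfr tile at 148040101 stayed called without each library in turn. The total was 10 without heterozygous 10-fold replicate 2, and 11 without heterozygous 10-fold replicate 1 or wild-type 10-fold replicate 2.

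Called tiles were concentrated around Mthfr. On the control diet, 10 of 51 (19.6%) lay within 20 Mb of the gene, against 2.70% of the tiles tested (Fisher's exact test, odds ratio 8.80, p 9.52e-07). On the 10-fold diet it was 5 of 18 (27.8%, odds ratio 13.9, p 9.17e-05). The test counts neighbouring tiles as independent, so its p-values for this window can be too small. Tiles called on either diet or over both numbered 13 at 7 loci in the window, and 50 at 38 loci elsewhere. Within Draxin, which encodes a secreted axon guidance protein (chromosome 4, 148102301 to 148102400), methylation was 5.48% ± 1.72 (SD, n = 5) in wild-type and 36.3% ± 11.7 in heterozygous controls, 30.8 points higher (adjusted p 6.73e-05). On the 10-fold diet it was 5.39% ± 1.31 against 31.3% ± 10.2, 25.9 points higher (adjusted p 0.0107), a call that ended without any one of 4 of the 10 libraries (adjusted p up to 0.129). The adjacent Draxin tile at 148102401 was 16.8 points higher on the 10-fold diet and was called without each library in turn. At both of these Draxin tiles the 2 CpGs measured carried the difference, whereas at Gm13223 it was 1 of 4 CpGs and at the Zfp982 tile 1 of 3. Over both diets, a comparison added after the data were examined, 48 tiles were called, 42 higher and 6 lower, and 10 of them lay within 20 Mb of Mthfr (odds ratio 9.50, p 5.24e-07). That total of 48 was 30 without replicate number 2, the lowest of the 5 values.

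**Figure D2:**
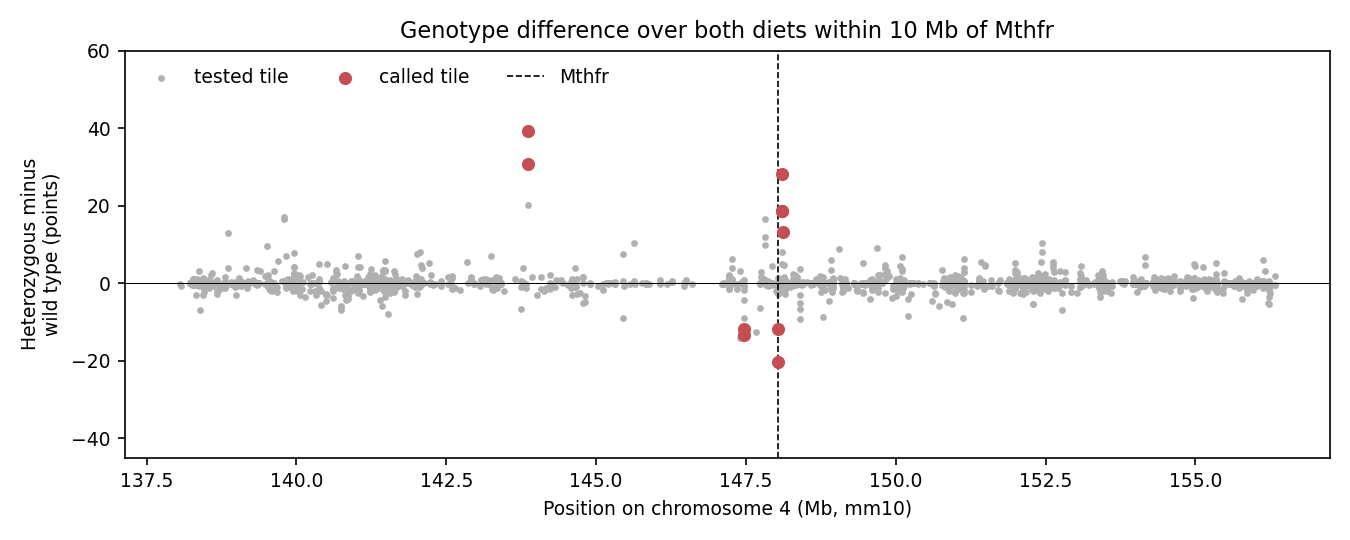
Difference in methylation (points, heterozygous minus wild type over both diets) of tiles by position on chromosome 4 (Mb, mm10), with Mthfr as a dashed line. The called Draxin tiles lie above 0 and the Mthfr tiles below 0.

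Mean levels of tile classes and gene lists were also compared between genotypes. On the control diet, all tiles averaged 26.9% ± 0.740 (SD, n = 5) in heterozygous and 0.687 points less in wild-type sperm (exact two-sided permutation p 0.167). Intermediate tiles, the 11,905 with a mean of 20 to 80%, averaged 55.8% ± 4.05 in heterozygous and 51.4% ± 4.42 in wild-type controls (difference 4.39 points, exact permutation p 0.135). That difference was 8.44 points among libraries above 50 M reads (2 against 3), 1.63 points among those below (3 against 2), and 2.03 points after adjustment for the share of reads in CpG-dense tiles (exact permutation p 0.5). On the 10-fold diet that difference was -3.21 points (exact permutation p 0.270). Genes of the DNA methylation machinery averaged 14.8% ± 0.714 in heterozygous and 13.5% ± 0.964 in wild-type controls, 1.32 points higher (exact permutation p 0.0635, adjusted 0.381). Of the 19 tiles of this list with an unadjusted p under 0.05, 18 were higher, in a comparison where 2379 of all 2454 tiles at that p and 10 or more points were higher, and 2 were called when adjusted over the list alone. Zfp57, which maintains imprints, averaged 31.6% ± 3.55 against 23.1% ± 5.93, and Mbd2, a methyl-CpG-binding protein gene, 13.9% against 11.1% (exact permutation p 0.00794, the smallest possible, among all list genes tested). Folate and one-carbon genes differed by 0.0192 points (exact permutation p 0.960), with 1 tile called when adjusted over the list alone. The differences were 0.156 points for germline genes, 0.255 for spermatid genes and 0.220 for developmental regulators, and maternally methylated imprinted promoters stood at 0.870% against 0.663%. On the 10-fold diet, folate genes were lower in heterozygous sperm by -0.617 points (exact permutation p 0.0714, adjusted 0.429), with 1 called tile, that of Mthfr, and 2 when adjusted over the list alone. The other lists differed there by -0.123 points (methylation machinery), -0.383 (germline), -0.325 (spermatid), -0.139 (developmental) and 0.0192 (maternal imprints).

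The comparison of heterozygous sperm on the 10-fold and control diets asks whether added folic acid lowers methylation when MTHFR is reduced, as the series title names hypomethylation. The quasi-binomial model called 0 tiles. At an unadjusted p under 0.05 there were 14,272 tiles, and 3322 of these differed by 10 or more points, of which 3252 were lower on the 10-fold diet. The limma test also called 0, and a chi-square test that ignores the spread between libraries 4005. The 2 tiles with an adjusted p under 0.05 (0.0282 each) had small differences, and both rose to 0.05 or more without any one of 7 of the 10 libraries (up to 0.242). Within Bsn, a presynaptic scaffold gene (chromosome 9, 108115701 to 108115800), methylation was 6.95% ± 0.868 (SD, n = 5) on the control and 0.738% ± 0.535 on the 10-fold diet, and at Gpr61, an orphan receptor gene, 2.24% ± 0.726 and 0.354% ± 0.294. Near Slc22a30 (chromosome 19, tile 8324101) it averaged 76.4% ± 4.47 on the control and 57.3% ± 5.23 on the 10-fold diet, a difference of -19.0 points (adjusted p 0.135).

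Intermediate tiles averaged 50.1% ± 3.48 (SD, n = 5) in heterozygous sperm on the 10-fold diet and 55.8% ± 4.05 on the control diet, a difference of -5.71 points (exact permutation p 0.0635, adjusted over 5 comparisons 0.317, with no adjustment over tile classes). All tiles averaged 26.001% ± 0.543 against 26.9% ± 0.740 (-0.922 points, exact permutation p 0.0635), and tiles outside genes 41.0% ± 0.719 against 42.5% ± 1.33 (-1.56 points, exact permutation p 0.0397, adjusted 0.198). Chromosome X was lower by -0.990 points (exact permutation p 0.0476, adjusted 0.238). The intermediate-tile difference was -11.4 points among libraries above 50 M reads (2 against 2) and -1.91 points among those below (3 against 3). Adjusted for the share of reads in CpG-dense tiles it was -3.55 points (SE 2.63, exact permutation p 0.286). Without heterozygous 10-fold replicate 3 or 4 the exact p became 0.0476. Across the 20 first-cohort libraries, the share of reads in CpG-dense tiles and the level of intermediate tiles were related (Pearson's r -0.570, permutation p 0.00937; Spearman's rho -0.587, permutation p 0.00771; adjusted 0.0125 and 0.0308 over 4 relations; r -0.570 without the 2 libraries farthest from the median share). Pearson's r was -0.784 in the 10 libraries above 50 M reads (permutation p 0.00686; rho -0.709, permutation p 0.0279) and -0.873 in the 10 below (permutation p 0.00227; rho -0.746, permutation p 0.0172). For deviations from group means it was -0.475 (permutation p 0.0346), and -0.316 without the 2 farthest libraries. That permutation mixed libraries across groups although the group means had been taken out, so its p can be too small.

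**Figure D3:**
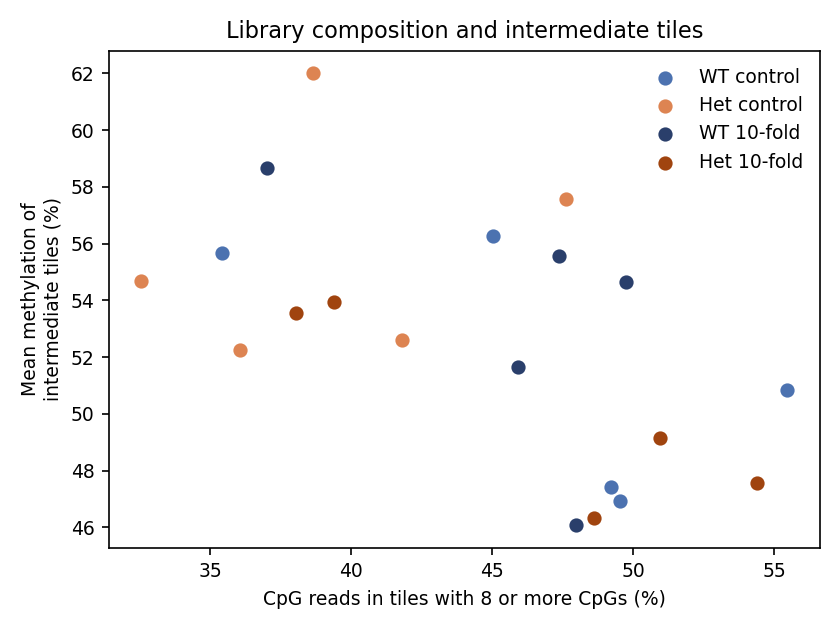
Mean methylation (%) of intermediate tiles against the share (%) of CpG reads in tiles with 8 or more CpGs, 1 point per first-cohort library, by group. Pearson's r over the 20 libraries is -0.570.

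**Figure D4:**
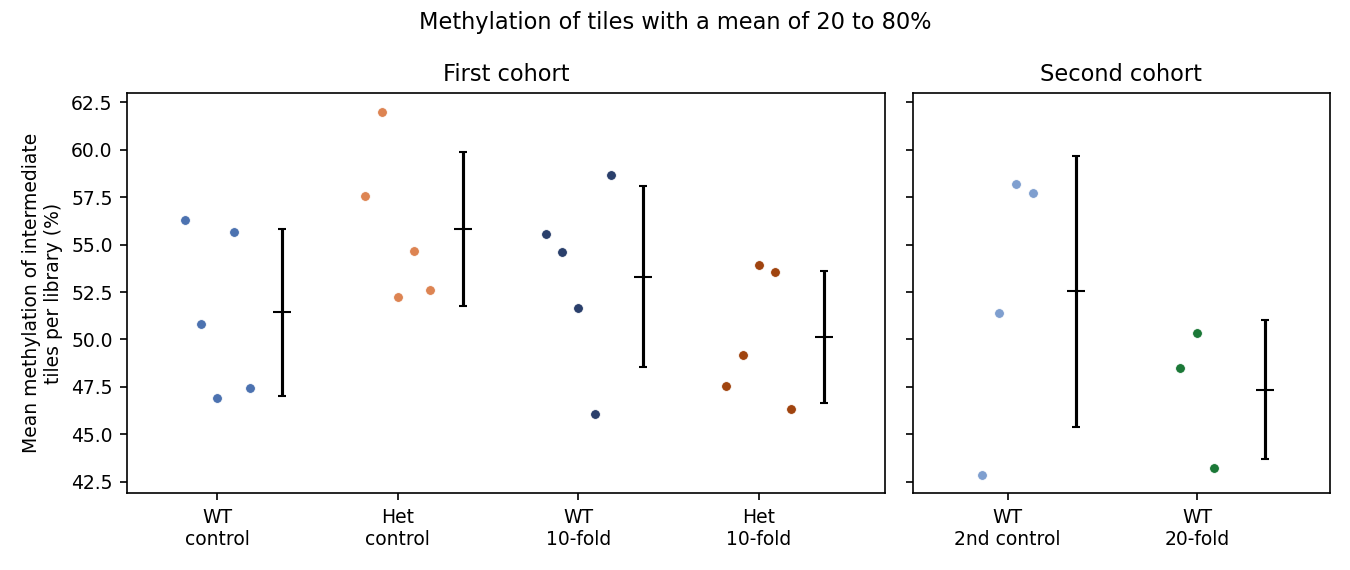
Mean methylation (%) of tiles with a mean of 20 to 80% in each library (points), by group, with group means and SD (bars). Heterozygous 10-fold libraries averaged 50.1% and heterozygous controls 55.8%.

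Dppa3, whose product protects methylation in the zygote, averaged 2.16% ± 1.36 (SD, n = 5) in heterozygous sperm on the 10-fold diet and 9.47% ± 2.19 on the control diet (exact permutation p 0.00794, the smallest possible and not adjusted). It was picked among all list genes after the values were seen, and its smallest tile adjusted p was 0.217 (0.0952 over the list alone). Wild-type sperm averaged 4.12% ± 2.75 and 9.84% ± 12.6, a difference of -5.71 points (exact permutation p 0.476). The methylation machinery list, to which Dppa3, Zfp57, Uhrf1 and Mbd2 belong, averaged 13.6% ± 1.16 on the 10-fold diet, lower by -1.16 points (exact permutation p 0.111, adjusted 0.317). All 20 of its tiles with an unadjusted p under 0.05 were lower, as were 3252 of all 3322 such tiles with 10 or more points, and 1 was called when adjusted over the list alone. Zfp57 averaged 24.05% against 31.6%, Uhrf1, a maintenance methylation factor, 9.64% against 13.03%, and Mbd2 12.3% against 13.9%. The lists differed by -0.323 points for folate genes, -0.418 for germline genes, -0.546 for spermatid genes (exact permutation p 0.0952), -0.248 for developmental regulators and -0.146 for maternal imprints.

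In wild-type sperm, the 10-fold and control diets were compared to ask for the effect of folic acid with normal MTHFR. The quasi-binomial model called 0 tiles, with a smallest adjusted p of 0.705, and limma called 0. At an unadjusted p under 0.05 there were 7776 tiles, 321 with a difference of 10 or more points, of which 300 were higher on the 10-fold diet. The chi-square test without spread called 726. Among the 5 smallest p-values, Zfp251 averaged 5.27% on the control and 9.33% on the 10-fold diet (4.05 points), Ptpn14 91.0% and 98.9% (7.84 points) and Fbrsl1 12.2% and 0.556% (-11.7 points). All tiles differed by 0.291 points (exact permutation p 0.563) and intermediate tiles by 1.89 points, to 53.3% ± 4.76 (SD, n = 5; exact permutation p 0.556). Folate genes were 0.314 points higher (exact permutation p 0.230, adjusted 0.905), with 1 tile called when adjusted over the list alone. Within that list the folate carrier gene Slc19a1 averaged 44.8% against 42.3% (exact permutation p 0.0159, not adjusted). It was picked among the list genes after the values were seen, and its smallest tile adjusted p was 0.591 over the list alone. The other lists differed by 0.279 points (methylation machinery), 0.122 (germline), 0.0334 (spermatid), 0.111 (developmental) and 0.0419 (maternal imprints), and the sign of the spermatid, germline and imprint values depended on single libraries or on the coverage minimum. Of the tiles at an unadjusted p under 0.05 with 10 or more points, the wild-type and heterozygous diet comparisons shared 0 of 300 and 70 higher tiles and 2 of 21 and 3252 lower tiles (Fisher's exact test for the lower, p 0.0975).

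The interaction of genotype and diet tests whether heterozygous sperm responded to the 10-fold diet differently from wild-type sperm. The model called 0 tiles (smallest adjusted p 0.212), limma 0, and the chi-square test without spread 5823. At an unadjusted p under 0.05 there were 14,002 tiles, and of the 4232 with a difference of 10 or more points, 4117 were lower. The tile with the smallest p lay within Mbd2 (-4.11 points), and Mboat7 (-16.8 points, adjusted p 0.227), Irf9 (-12.5), Bsn (-6.82) and Pcbd1 (-6.05) followed. Intermediate tiles gave -7.60 points (exact permutation p 0.0603, adjusted 0.161) and all tiles -1.21 points (exact permutation p 0.0636). In simulated data the interaction test recovered 20.9% of tiles raised by 20 points and 66.7% of those raised by 40 points. Losses were not simulated. A diet comparison over both genotypes, added after the data were examined, also called 0 tiles by the model and by limma, with 8760 at an unadjusted p under 0.05, and the chi-square test called 489.

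The 20-fold diet was compared with the second-cohort control diet in wild-type sperm. The model called 0 tiles (smallest adjusted p 0.241). In simulated data, which held gains only, it recovered 1.52% of tiles changed by 40 points. Among tiles with a mean of 5 to 95%, it recovered 10.4% of those changed by 20 points and 40.9% of those changed by 40 points, and called 0 of the 26,176 such tiles in the real data. At an unadjusted p under 0.05 there were 24,779 tiles. Of the 2196 with a difference of 10 or more points, 1770 were lower. The chi-square test without spread called 5165 and limma 326 (91 higher, 235 lower), a count that became 0 once each library's mean was subtracted. The sonic hedgehog gene Shh held 2 of the 5 smallest p-values (chromosome 5, tiles 28458101 and 28458201), where methylation was 2.15% ± 0.210 (SD, n = 4) on the control and 0% ± 0 (n = 3) on the 20-fold diet, and 3.27% ± 0.268 and 0.0983% ± 0.105. Adarb2 averaged 29.9% ± 2.43 and 10.3% ± 1.56, and Gm5251 79.0% ± 2.84 and 46.0% ± 3.24 (adjusted p 0.241 for each).

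With 4 against 3 libraries, 0.0571 is the smallest exact two-sided p for the 20-fold diet. All tiles averaged 13.8% ± 0.388 (n = 3) on the 20-fold and 14.6% ± 0.923 (n = 4) on the control diet (exact permutation p 0.286), intermediate tiles 47.4% ± 3.68 and 52.5% ± 7.15 (exact permutation p 0.286), and tiles below 20% averaged 0.908% ± 0.0825 and 1.39% ± 0.331 (exact permutation p 0.0571). Maternally methylated imprinted promoters averaged 0.291% ± 0.233 and 1.13% ± 0.238 (exact permutation p 0.0571, adjusted 0.206), with 0 called tiles. All 14 of their tiles with an unadjusted p under 0.05 were lower, 2 of them called when adjusted over the list alone. Developmental regulators, to which Shh belongs, averaged 1.85% against 2.13%, with 285 of 298 such tiles lower and 2 called when adjusted over the list alone. Folate genes were lower by -0.536 points (39 of 40 such tiles lower), methylation machinery genes by -0.721 (38 of 43), germline genes by -1.08 and spermatid genes by -0.499 (1 tile called when adjusted over the list alone). Losses were not particular to these lists. The class of tiles below 20% differed by -0.486 points, and 1770 of all 2196 tiles at an unadjusted p under 0.05 with 10 or more points were lower. What lowered these values was not tested. The thymidylate synthase gene Tyms averaged 87.0% ± 0.0620 (n = 3) against 93.4% ± 1.51 (n = 4), the folate transporter gene Slc46a1 18.9% against 25.1%, and Dnmt1 20.7% against 23.1%. In the other direction, the only tile of Bhmt averaged 12.2% ± 21.1 against 1.44% ± 2.88 (exact permutation p 0.857), the largest difference among folate genes. The germline gene Rec8 averaged 97.0% against 93.3%, and Tex14 13.1% against 9.52%. The groups did not overlap in the share of reads in CpG-dense tiles, so that this share and the diet could not be separated.

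The difference between the 20-fold and 10-fold effects in wild-type sperm was tested over 82,925 tiles with enough reads in both cohorts. Each dose has its own controls by the titles, so dose could not be separated from other differences between the cohorts, as divided here. The share of reads in CpG-dense tiles was 46.9% in first-cohort wild-type controls and 45.6% in the wild-type 10-fold group. It was 69.0% in second-cohort controls and 77.4% in the 20-fold group. The model called 0 tiles (smallest adjusted p 0.0850), limma 0 and the chi-square test without spread 2961. At an unadjusted p under 0.05 there were 12,689 tiles. Of the 1482 with a difference of 10 or more points, 1227 had a lower 20-fold than 10-fold effect. The smallest p-values were at Gm11500 (16.4 points), Cers1 (-1.97), Lhfp (-12.2), Mapk15 (-3.41) and Gm14569 (16.7). Simulated gains of 40 points were recovered in 37.9% of tiles, and losses were not simulated.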

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

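Of the tests in this part, those of depth and incomplete conversion for intermediate tiles, those of single-CpG variants apart for gains and losses near Mthfr, that of somatic cells and that of the sign on the other diet were chosen after the results were seen.

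In 6 of 175 groups of values, 1 library lay far from the others of its group by Dixon's test, where chance gives about 1 in 20. The folate list averaged 17.97% in wild-type 10-fold replicate 4, against 18.8 to 19.1% in its group. Maternally methylated imprinted promoters averaged 1.37% in heterozygous 10-fold replicate 4, against 0.401 to 0.652%. Tiles above 80% averaged 89.97% in second-cohort control replicate 1, against 92.6 to 92.9%. The Septin8 tile at 53555801 stood at 3.2% in wild-type 10-fold replicate 4, against 9.72 to 12.3%. In wild-type 10-fold replicate 5, the Slc22a4 tile at 54035301 stood at 42.9%, against 12.0 to 18.4%, and the Draxin tile at 148102401 at 2.52%, against 1.34 to 1.67%.

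Outside the chromosomes compared, the unplaced sequence JH584304 was methylated at 15.1% in heterozygous control replicate 2 and 14.5% in replicate 4, above the 7.95% that was the highest wild-type control. The groups averaged 9.07% ± 5.32 (SD, n = 5) and 4.46% ± 1.99 (exact permutation p 0.111), and the heterozygous 10-fold group 4.35% ± 0.834. No explanation was tested.

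Intermediate tiles were lower by -5.71 points in heterozygous sperm on the 10-fold diet than on the control diet. Incomplete bisulfite conversion of the controls would raise unmethylated tiles by 11.3 points, and they were higher by 0.343 points, which argues against it. Library composition stays open: the difference adjusted for the share of reads in CpG-dense tiles was -3.55 points (SE 2.63), within reach of 0 and of the unadjusted value. Sequencing depth stays open too: the difference was -11.4 points above 50 M reads (2 libraries in each group) and -1.91 below (3 in each), and its value adjusted for log2 reads, -5.64 points (SE 2.76), decides nothing, since that adjustment moved no difference of a tile class by more than 0.114 SE. An effect of folic acid under reduced MTHFR may underlie it, and cannot be told apart from composition, depth or chance (exact permutation p 0.133 within the depth classes).

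Within 20 Mb of Mthfr, 13 tiles differed between genotypes in at least 1 diet or over both, from 143860101 to 148115701 on chromosome 4. A candidate explanation is DNA of the strain in which the gene was targeted, where sequence variants that remove a CpG look like methylation differences. Of the 5 lower tiles with 2 or more CpGs measured (Gm13223, Zfp982 and Mthfr), the difference was carried by 2 or more CpGs in 0%, which is what such variants give. Of the 7 higher tiles measured, 85.7% had 2 or more CpGs carrying the difference, which argues against single variants in those tiles. The exception was the Draxin tile at 148115701, where 1 of 2 CpGs carried it. Both together give 50% of 12 tiles, which decides nothing for the region as a whole, and no variant or allele was measured directly.

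Elsewhere, 50 tiles at 38 loci differed between genotypes, 48 higher and 2 lower in heterozygous sperm. Single-CpG variants are argued against by the 98.0% of 49 tiles where 2 or more CpGs carried the difference, and somatic cells by imprinted promoters, at which heterozygous exceeded wild-type sperm by 0.113 points. Loci that vary between any sets of mice were tested for the 13 tiles called on the 10-fold diet. Of their 11 loci, 100% had the same sign in the control-diet libraries (95% exact interval from 71.5%). That test assumes equal chances of either sign. On the control diet, however, 2379 of the 2454 tiles at an unadjusted p under 0.05 and 10 or more points were higher. A shared sign of gains therefore decides nothing. The 2 losses, near Gm6308 and Gm32427, kept their sign against that direction, but are too few to decide. Of the 41 called on the control diet, 34 kept their sign on the 10-fold diet (26 of 32 loci, 81.25%, 95% exact interval 63.6 to 92.8%, exact binomial p 0.000535), more than such loci alone would give, so they stay open for a part of the tiles, such as the 7 with the other sign (Sstr3 and Slc22a30 among them), while second-cohort wild-type libraries lay nearer to the wild-type mean in 82.9% of 35 tiles, too few by the share set in advance to exclude them. Among the 21 of those tiles with a difference of 20 or more points, it was 20, but the share set in advance did not include that restriction. Lower methylation of the second cohort in general would also raise both shares, since 48 of the 50 tiles were higher in heterozygous sperm. Also open are reduced MTHFR and a hypothesis not measured here, that alleles of zinc finger genes near Mthfr (17 of 140 protein-coding genes within 5 Mb) were inherited with the mutation and could act on other chromosomes, for which 66% of the tiles lay outside genes, against 27.8% of those tested and 54.3% of intermediate ones.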

How the results depend on the processing

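Alternatives added after the data were examined were the depth block, the composition covariate, the 5 to 95% tiles, the depth sets and the overlap from separate fits. Of the alternatives other than leaving out a library, 190 of 201 values of class and library means, 143 of 150 of list means and 961 of 1056 of named tiles kept their direction and their side of the threshold, and 107 of 135 counts of tiles stayed at 0 or within 1.5 times. The causes of the changes below were not tested. Where fewer tiles or libraries are named, that describes the setting and was not tested as the cause.

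With the spread between libraries ignored, counts rose to 726 (wild-type 10-fold diet), 4005 (heterozygous 10-fold diet), 3061 (genotype, control diet), 1539 (genotype, 10-fold diet), 5823 (interaction), 5165 (20-fold diet), 2961 (20-fold against 10-fold), 346 (genotype, both diets) and 489 (diet, both genotypes). For the heterozygous 10-fold diet, no minimum difference gave 2 tiles and the 5 to 95% tiles 61. The 51 tiles of genotype on the control diet became 33 at 20 points, 29 at 30 reads (fewer tiles), 11 with only the 2 groups in the fit (fewer libraries), 27 with the library number as block, 18 with the composition covariate, 217 in 5 to 95% tiles (17 false calls in simulated data, against 5 over all tiles), 17 for single CpGs, 15 with limma and 14 with limma centred. The 18 tiles on the 10-fold diet became 9 at 30 reads (fewer tiles), 4 with only the 2 groups (fewer libraries), 31 in 5 to 95% tiles with the composition covariate, 2 for single CpGs and 11 with limma centred. For the 20-fold diet limma called 326. Within 10 Mb of Mthfr lay the same 10 and 5 called tiles as within 20 Mb (odds ratios 15.3 and 24.01), and with no minimum difference the genotype lists, of 55 and 15 higher tiles, shared 14. With only the 2 groups in each fit (fewer libraries), the genotype lists shared 3 higher tiles in place of 14, and 0 lower ones, since the control-diet list held none. The 48 tiles of genotype over both diets became 24 at 30 reads and 30 with limma centred.

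Some small values reversed. In the wild-type 10-fold diet comparison, spermatid genes gave -0.0636 points at 30 reads, and maternal imprints -0.0314 at 30 reads, -0.0443 weighted by coverage and -0.0745 for single CpGs. Maternal imprints gave -0.0281 at 10 reads for genotype on the 10-fold diet. The composition covariate turned the 20-fold values to 1.31 points (all tiles) and 10.4 (intermediate tiles, SE 13.1), with groups that do not overlap in composition. Intermediate tiles on the heterozygous 10-fold diet gave -6.13 points at 10 reads and -7.88 weighted by coverage (exact permutation p 0.0476).

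Leaving out single libraries gave 20 to 74 tiles for genotype on the control diet (20 without wild-type control 2, 23 without 3, 21 without heterozygous control 2) and 10 to 19 on the 10-fold diet (10 without heterozygous 10-fold 2, 11 without heterozygous 10-fold 1 or wild-type 10-fold 2), while leaving out a replicate number from all groups gave 30 to 39 over both diets. The list values that changed sign ranged, in points, from -0.127 to 0.155 (folate, genotype on the control diet), -0.00567 to 0.328 (germline, same), -0.529 to 0.152 (methylation machinery, genotype on the 10-fold diet) and -0.143 to 0.129 (maternal imprints, same), -0.308 to 0.0530 (maternal imprints, heterozygous 10-fold diet), and, for the wild-type 10-fold diet, -0.0521 to 0.259 (germline), -0.102 to 0.224 (spermatid), -0.0680 to 0.163 (maternal imprints), -0.0962 to 0.365 (chromosome X) and -0.0226 to 0.153 (below 20%). Tiles above 80% on the 20-fold diet ranged from -0.280 to 0.702. On the heterozygous 10-fold diet, intermediate tiles ranged from -6.67 to -4.17 and all tiles from -1.08 to -0.635, both with an exact p of 0.0476 without replicate 3 or 4 of the 10-fold group.

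Correlations of same-numbered libraries (-0.0182 to 0.400 for wild-type and heterozygous controls) were not all above 0.1, the level set for a pairing, in any pair of groups. The numbers were therefore not taken to pair the libraries. For wild-type and heterozygous controls, however, the median was 0.262 for same-numbered and -0.0764 for other libraries. A relation by number therefore cannot be excluded there. On the 10-fold diet the medians of both genotypes were -0.121 and 0.0284. With the replicate number as a block, 35 tiles were called for genotype on the control diet (31 of the 51 among them), 15 on the 10-fold diet (13 of the 18) and 38 over both diets. The block kept -5.71 points for intermediate tiles on the heterozygous 10-fold diet, with an exact sign-flip p of 0.188. At a median of 276 reads per tile and library, the 20-fold comparison recovered 1.52% of simulated gains of 40 points over all tiles and 40.9% in 5 to 95% tiles.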

Other observations

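Among tiles with a mean of 5 to 95%, a restriction added after the data were examined, heterozygous sperm on the 10-fold diet held 61 called tiles, all lower than on the control diet, and wild-type sperm 0 (0 with limma over all tiles, 7776 there at an unadjusted p under 0.05). In simulated data for genotype on the control diet, the same restriction gave 17 false calls among 33,033 unchanged tiles, with 7.40% of them at an unadjusted p under 0.05, so its adjusted p can be too small. No such simulation was made for this comparison. The tiles were chosen after their values were seen. The largest losses were at Rhbdf1 (-42.3 points; chromosome 11, 32214401), Gm9682 (-33.4), Glo1 (-31.9; chromosome 17, 30606601), Calhm1 (-31.5), Rn18s-rs5 (-29.3), the receptor gene Erbb3 (-28.8; chromosome 10, 128569601) and Nt5c1a (-27.8). Snhg14 (-23.2), the somatostatin receptor gene Sstr3 (-19.6), Slc22a30 (-19.0) and Epcam (-17.5) were also lower, with adjusted p of 0.0408 to 0.0489. With library composition as a covariate 0 of these tiles were called, and the interaction of genotype and diet called 0 in this set.

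Several genotype calls lay within genes, also chosen after their values were seen. Itprip (chromosome 19, tile 47894701) averaged 34.7% in wild-type and 74.97% in heterozygous controls (adjusted p 0.0213) and 35.2% and 59.8% on the 10-fold diet. Brd3, a bromodomain gene, averaged 2.06% and 19.8% in controls and 1.71% and 16.9% on the 10-fold diet. Sstr3 averaged 21.7% and 42.4% in controls, but 24.8% and 22.7% on the 10-fold diet.

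Other splits of the same libraries were called or counted in the same way, a test planned before the data were examined except for the comparisons over both diets and over both genotypes. No share is adjusted over the 9 comparisons, so "excluded" below means at 0.05 before such an adjustment. Where 100 splits were drawn, the share among all possible ones can differ, so a share near 0.05 settles little. For genotype on the control diet, 3 of 100 splits, drawn from 126, gave 51 or more called tiles, a share under 0.05 but near it. The highest other split gave 497, several times the real count, which points to a structure of the samples. Its groups differed by 10.2 points in the share of reads in CpG-dense tiles, against 7.60 points in the real split. For genotype on the 10-fold diet, 1 of 100 splits, the real one, gave 18, and the highest other gave 2, so chance can be excluded. For genotype over both diets, 2 of 100 splits, drawn from 31,752, gave 48 or more, again a share under 0.05 but near it. The highest other gave 221, which again points to a structure of the samples. Its control-diet groups differed by 5.15 points in the share of reads in CpG-dense tiles, less than the 7.60 points in the real split. That share therefore does not set this split apart.

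The comparisons with 0 called tiles were counted at an unadjusted p under 0.05 and 10 or more points. For the heterozygous 10-fold diet, 6 of 100 splits gave 3322 or more (highest other 4080), and chance cannot be excluded. The interaction gave 4232, with 4 of 100 splits, drawn from 31,752, as large and 7314 the highest other. That share is under 0.05, but too near it for the drawn splits to exclude chance. Nor can chance be excluded for the mean levels, by exact permutation tests over 63,504 relabellings (p 0.0603 for intermediate and 0.0636 for all tiles, adjusted p 0.161). The model called 0 tiles (14,002 at an unadjusted p under 0.05), as did limma. Library composition stays open here too, since the share of reads in CpG-dense tiles differed by 6.95 points between the heterozygous diet groups, against 5.61 in the highest other split. Chance cannot be excluded for the wild-type 10-fold diet (321, 56 of 100, highest other 3130), where the highest split again points to a structure, nor for the 20-fold diet (2196, 6 of 35, highest other 3207). Nor can it for the 20-fold against the 10-fold effect (1482, 12 of 100, highest other 2697) or for diet over both genotypes (263, 42 of 100, highest other 1905, which again points to a structure). For the wild-type 10-fold diet, the share of reads in CpG-dense tiles differed by 8.24 points in the highest other split, against 1.33 in the real one. For diet over both genotypes it differed by 5.71 points between the heterozygous groups, against 6.95 in the real split.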
